A study of Schizosaccharomyces pombe with 3 samples.

How the data were processed

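Small RNA from 3 fission yeast strains was analysed, 1 library per strain: wild type, NLS-swi6-KR25A and dcr1 delta. Per the labels' protocols, total RNA was extracted with hot phenol from cells growing exponentially in rich medium, the small fraction was separated on a column, RNA of 18 to 28 nucleotides was taken from a gel, and libraries were made with a TruSeq small RNA kit. The deposited values are counts: for each distinct read sequence, the number of reads with exactly that sequence, without normalization, per the values of the authors' files. CASAVA 1.8 was used, per the submitters' processing notes. The adapter trimming, any filter, and the aligner and genome build used by the authors are not given in the sources used here.

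Everything else was computed here from those counts. Each distinct sequence, of 14 to 50 bases, was matched to the Schizosaccharomyces pombe assembly ASM294v3 with bwa 0.7.19 (aln and samse). Perfect matches were taken first, and sequences of at least 18 bases without one were allowed 1 mismatch. All positions of the best kind were kept, up to 5000, and the reads of a sequence were split equally between them. A position was assigned to a class, region or gene by its central base. Reads with a mismatch made up 6.22% of mapped reads in wild type, 3.83% in NLS-swi6-KR25A and 5.54% in dcr1 delta, and reads with 1 position made up 44.5%, 44.9% and 44.9%. Tables and intervals were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots with matplotlib 3.10.9.

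Centromeres were taken as the spans between the flanking protein-coding genes: per1 and emc5 (chromosome I, 3751730 to 3790923), rpb1 and yox1 (chromosome II, 1596745 to 1648231) and chk1 and ppc1 (chromosome III, 1064444 to 1142615). Subtelomeres were the outer 50000 bases of chromosomes I and II. The planned interval from mat2 to mat3 could not be used, because the assembly used here lacks it, and the span from rpp202 to emc3 around mat3 was used instead. Reads of the centromere-like repeat of that locus cannot be told from those of the centromeric repeats. The tRNA genes inside the centromeres were left out on both strands, a choice made after the data were seen. An edge of a centromere was the outermost stretch of 1500 bases starting at a window of 250 bases with at least 10 wild-type RPM and, in dcr1 delta, at most 1 part in 10 of it. That definition was also set after the loss in NLS-swi6-KR25A had been seen.

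Depth ranged from 18225027 mapped reads in wild type to 32896933 in NLS-swi6-KR25A, with 23587252 in dcr1 delta. With 1 library per group, each mutant library was compared with the wild-type library by the ratio of RPM, and no test across replicates was possible. Intervals are exact 95% Clopper-Pearson intervals on the share of the pooled count, with counts rounded to whole reads and counts under 3 set to 3. They cover counting error only. Shares have exact binomial intervals. Genes were counted on the sense and antisense strand apart and compared where 1 of the pair of libraries had at least 100 reads. A gene strand was called higher or lower where the ratio was at least 2-fold and its interval excluded 1. The wild-type library is shared by both comparisons, so no overlap between them is given.

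The genes named in the text followed a rule written before the data were examined. They were the 12 highest and the 12 lowest ratios among called gene strands, plus dcr1, swi6, tlh1 and tlh2, and of each fixed list up to 4 members with most reads. Exceptions are stated where they occur. The 12 gene lists were fixed in advance, and all 296 members were matched, 1 of them by a synonym (mcp5). A list is described by its median log2 ratio and the percentile of that median among 10000 random lists, each member being drawn from the 100 gene strands closest in mean expression. These were sense strands of nuclear genes of every RNA class, not of protein-coding genes alone. The position search, calls, intervals and list percentiles were tested on simulated data. The true position was among the hits for 100% of 16010 simulated reads without a mismatch and 99.9% of 3990 with 1 mismatch. For NLS-swi6-KR25A, 100% of 198 genes changed 3-fold were called, as were 0.0171% of 5833 unchanged ones, and 95.7% of 6031 intervals held the true ratio. The dcr1 delta values were 100% of 197, 0% of 4725 and 95.9% of 4922. Simulated counts were drawn with Poisson counting error alone around the wild-type values. These rates therefore do not cover variation between cultures or libraries.

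Alternatives fixed in advance were scaling by mapped reads other than rRNA and tRNA, by the median of ratios over 8249 gene strands and by snRNA, snoRNA and structural non-coding RNA, and restriction to reads of 20 to 24 bases, to reads with 1 position or to perfect matches. Further ones counted each position in full, counted each distinct sequence once, or used 30 or 500 reads or a 4-fold ratio for calls. The restriction to reads of 18 to 28 bases and the other treatments of tRNA genes were added after the data had been seen. Adapter remnants were not trimmed further: 135869 reads in wild type, 6989 in NLS-swi6-KR25A and 24915 in dcr1 delta ended with ACAGTCCGACGATC, the end of the adapter. Reads without a position (7.76% in wild type, 5.33% in NLS-swi6-KR25A and 6.98% in dcr1 delta) were left out of the comparisons.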

Results

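Small RNA was sequenced from 3 strains of the fission yeast Schizosaccharomyces pombe in exponential growth, with 1 library per strain: a wild type carrying swi6+, a strain carrying the swi6 allele NLS-swi6-KR25A, and a strain deleted for dcr1. The gene dcr1 encodes Dicer, the ribonuclease that cuts double-stranded RNA into small interfering RNA, and swi6 encodes the heterochromatin protein HP1, which binds methylated histone H3. In the KR25A allele, basic residues in the hinge of Swi6 are replaced by alanine, a change known to impair RNA binding, and a nuclear localization signal is added. The RNA had been taken from a gel between 18 and 28 nucleotides. The libraries held 19759054 reads for wild type, 34749806 for NLS-swi6-KR25A and 25357237 for dcr1 delta, of which 92.2%, 94.7% and 93.0% had a position in the genome. Values are in RPM, the usual scaling of read counts to the mapped reads of each library, with reads at several positions split equally between them. No group had a replicate, so each comparison describes a pair of libraries rather than the strains, and no p-value is given. The 95% intervals in brackets, and the floor of 3 reads, cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. For ratios, counts were rounded to whole reads and counts under 3 were set to 3. The floor corresponded to 0.165 RPM in wild type, 0.0912 RPM in NLS-swi6-KR25A and 0.127 RPM in dcr1 delta.

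The deleted gene was examined first. The coding part of dcr1 (chromosome III, 1506166 to 1510290) held 67 sense reads in wild type, 138.5 in NLS-swi6-KR25A and 0 in dcr1 delta. With the floor, its sense RPM was 28.9-fold lower in dcr1 delta than in wild type (ratio 0.0346, 0.00696 to 0.106). Its ratio in NLS-swi6-KR25A was 1.14 (0.846 to 1.55). The transcribed stretch downstream of the coding part (1504949 to 1506165) held 34, 38 and 162 sense reads in the same order, and reads there check nothing about the deletion. For swi6 (chromosome I, 1702406 to 1704098), 144 sense reads were found in wild type, 350 in NLS-swi6-KR25A and 510 in dcr1 delta. Read counts cannot check a tagged, point-mutated allele.

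Fragments of abundant RNA made up most of every library. Reads of rRNA and tRNA together accounted for 55.0% of mapped reads in wild type, 54.4% in NLS-swi6-KR25A and 57.5% in dcr1 delta, and mitochondrial reads for 31.1%, 31.7% and 25.9%. Centromeric reads, with tRNA genes left out, accounted for 3.51% (3.50 to 3.52), 2.60% (2.60 to 2.61) and 0.0492% (0.0483 to 0.0501). The sense strand of mRNA held 8.20%, 8.71% and 13.5% of mapped reads. In wild type, 80.9% of the reads of the centromere were 20 to 24 nucleotides long, 23 nucleotides was their most frequent length and 69.8% of them began with U. The NLS-swi6-KR25A library gave 79.9%, 22 nucleotides and 70.0%, with 49.7% (49.6 to 49.8) of its centromeric reads on the plus strand. In dcr1 delta the corresponding values were 62.3% (61.4 to 63.2), 20 nucleotides, 34.8% (33.9 to 35.7) and 52.3% (51.4 to 53.2). Sense mRNA reads began with U in 34.3% (wild type), 35.5% (NLS-swi6-KR25A) and 35.6% (dcr1 delta) of cases.

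**Figure D1:**
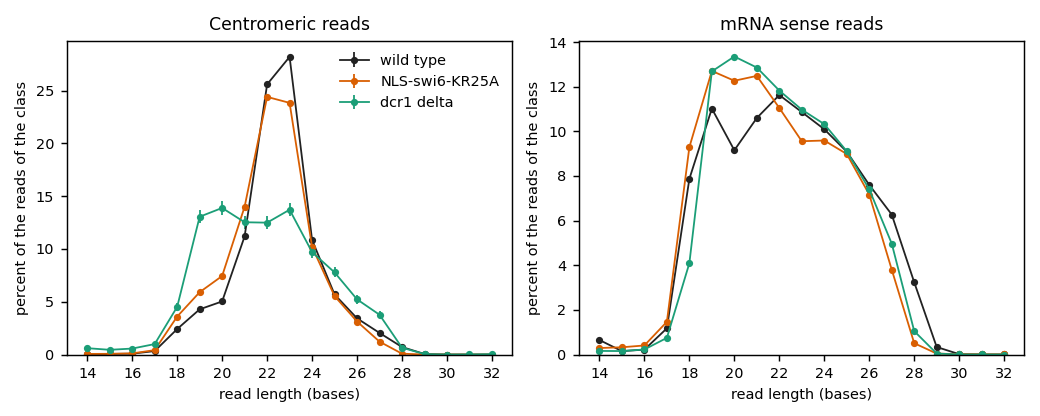
Percent of the reads of a class (y axis) at each read length in bases (x axis) for centromeric reads (left) and sense mRNA reads (right) in the 3 libraries, with points joined by lines and 95% binomial intervals as bars. Centromeric reads of 22 and 23 bases made up 53.8% of the class in wild type, 48.2% in NLS-swi6-KR25A and 26.2% in dcr1 delta.

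The comparison of dcr1 delta with wild type asked which small RNAs differed in the absence of Dicer. Small RNA from the outer repeats of all 3 centromeres was nearly gone in dcr1 delta, and so was small RNA from the ends of chromosomes I and II that carry the helicase genes tlh1 and tlh2. Centromeric small RNA was at 35114 RPM in wild type and 492 RPM in dcr1 delta, a 71.4-fold lower level (ratio 0.0140, 0.0137 to 0.0143). Fragments of mRNA took a larger share of the dcr1 delta library (ratio 1.65, 1.64 to 1.65), as did those of snoRNA (1.57), and the median protein-coding gene stood 0.80 higher on the log2 scale (1.74-fold).

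By centromere, the ratio of dcr1 delta to wild type was 0.0108 (0.0103 to 0.0112) at centromere 1, 0.0157 (0.0151 to 0.0163) at centromere 2 and 0.0147 (0.0143 to 0.0150) at centromere 3, each taken as the span between the flanking protein-coding genes. Per annotated gene and strand, 175 of the 233 centromeric features with at least 100 reads in either library were at least 2-fold lower in dcr1 delta and 0 were at least 2-fold higher. These features include the tRNA genes that the regional values leave out. By strand, 88 of 142 sense and 87 of 91 antisense strands were lower. The non-coding RNA SPNCRNA.7235 (chromosome III, 1140813 to 1141069) went from 784 to 0.212 RPM on its sense strand, a ratio of 0.000270 (8.77e-05 to 0.000631), and on its antisense strand to 0.000754 (0.000245 to 0.00176). Its neighbour SPNCRNA.7236 (1141320 to 1142247) had a sense ratio of 0.000313 (0.000101 to 0.000730), and SPNCRNA.7234 (1140398 to 1140608), with 1 read left, 0.000450 (9.27e-05 to 0.00131). On the other side of centromere 3, SPNCRNA.7185 (1070099 to 1070326) kept 1 read per strand, with ratios of 0.000452 (9.32e-05 to 0.00132) sense and 0.000783 (0.000161 to 0.00229) antisense. Of the sense reads, 7.97% had 1 position for SPNCRNA.7234 and 4.90% for SPNCRNA.7185. Inside the centromeres, the sense strands of SPNCRNA.3674 and SPNCRNA.3687 (centromere 1), SPNCRNA.5272 (centromere 2), and SPNCRNA.7202 and SPNCRNA.7211 (centromere 3) had ratios between 0.000551 and 0.000772. Of the reads of SPNCRNA.3674, 20.7% had 1 position, and those of the others in this group matched several repeats, so the copy of origin is uncertain. With tRNA genes kept, the centromeric log2 ratio was -0.55 rather than -6.16, and with tRNA genes left out on their annotated strand only it was -4.88, because reads opposite the tRNA-Asp gene SPBTRNAASP.05 in centromere 2 (chromosome II, 1602347 to 1602417) were at 727 RPM in wild type and 721 RPM in dcr1 delta. The main definition, with tRNA genes left out on both strands, was chosen after these reads had been seen.

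At the ends of chromosomes I and II, the outer 50000 bases together went from 1045 to 148 RPM (ratio 0.141, 0.136 to 0.147). The left end of chromosome I (ratio 0.0737) and the right end of chromosome II (0.0470), which carry tlh1 and tlh2, were 13.6-fold and 21.3-fold lower. The right end of chromosome I had a ratio of 0.400 (0.373 to 0.428), and the left end of chromosome II one of 0.979 (0.891 to 1.08). Both strands of tlh1 (chromosome I, 1 to 5662) were lower, with a sense RPM 33.8-fold lower and an antisense RPM 236-fold lower, and tlh2 (chromosome II, 4526885 to 4532899) gave 32.3-fold and 238-fold. Reads of these near-identical helicase genes cannot be told apart. The ends that carry them also share reads, so their values are not separate measurements. Of subtelomeric features, 34 of 42 were at least 2-fold lower and 4 at least 2-fold higher. With the shift of the median protein-coding gene (0.80 on the log2 scale) removed, 34 were lower and 0 higher. Among subtelomeric reads with 1 position the log2 ratio was -0.41, against -2.82 for all. Around mat3 at the mating-type locus (chromosome II, 2128468 to 2138318), 30 reads in wild type and 64.8 in dcr1 delta gave a ratio of 1.67 (1.07 to 2.67), or 0.02 on the log2 scale with median-of-ratios scaling. The reference used here lacks the centromere-like repeat between mat2 and mat3, so that no value is given for it.

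Outside these regions, dcr1 delta changes were read against the general shift of 0.80. Without removing it, 1561 of 6524 gene strands outside the centromeres and subtelomeres were at least 2-fold higher and 8 lower (1565 and 217 of all 6799). With the shift removed, 33 were higher and 126 lower (33 and 358 of all), and scaling by the median of ratios gave 47 higher and 78 lower (47 and 301 of all). Scaling by snRNA, snoRNA and structural non-coding RNA gave 128 higher and 17 lower (128 and 227 of all), and scaling by mapped reads other than rRNA and tRNA gave 2233 and 7 (2238 and 216 of all), so that the split between higher and lower genes changed with the scaling. The features with the highest ratios stood above the shift. The snoRNA snoR58 (chromosome I, 5366223 to 5366297) went from 2.09 to 22.5 RPM, 10.8-fold (7.75 to 15.4) or 6.19-fold relative to the shift. The snoRNAs snoR02 (5.82-fold, 3.34-fold relative) and snoZ3 (4.49-fold, 2.58-fold relative) were also higher. Sense reads of ecl1, named for its extension of chronological lifespan, were 8.62-fold higher (6.15 to 12.4; 4.95-fold relative), those of urh1, a uridine ribohydrolase, 8.14-fold (4.61 to 15.7; 4.68-fold relative) and those of cta3, a cation-transporting ATPase, 7.16-fold (4.45 to 12.2; 4.11-fold relative). Antisense reads of SPNCRNA.7727 (7.31-fold), SPNCRNA.1374 (4.02-fold relative to the shift) and alg3 (5.68-fold) include sense reads of ecl1, cta3 and snoR02, which lie opposite them, and are not independent of those genes. Antisense reads of SPNCRNA.4542 (6.25-fold), SPNCRNA.1585 (4.51-fold) and SPNCRNA.1279 (4.15-fold) completed the 12 highest.

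Several fixed groups of genes stood near the shift in dcr1 delta. Of 19 RNAi and heterochromatin factors with enough reads, 6 were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.81. They were swi6 (2.74-fold, 2.27 to 3.32), rik1 (2.10-fold, 1.67 to 2.66), a subunit of the complex that methylates histone H3, and chp1 (3.09-fold, 2.29 to 4.23), clr4, sir2 and ago1, of which the last 4 were named after their values had been seen. The histone deacetylase gene clr3 (1.44-fold) and epe1 (1.86-fold), which counteracts silencing, stayed under 2-fold. Relative to the shift, swi6 was at 1.57 and rik1 at 1.21. Antisense reads of swi6 were at 6.93 RPM against 1.70, 4.09-fold (2.77 to 6.21) or 2.35-fold relative to the shift. RNA elimination factors had a median of 0.80 and 3 of 9 members over 2-fold: mtr4, the exosome helicase (2.17-fold), mmi1 (2.12-fold), which recognises meiotic transcripts, and mtl1 (2.02-fold). The exosome nuclease gene dis3 was at 1.77-fold. Histones had a median of 0.72 with 1 of 10 over 2-fold (hht2 at 2.11-fold, named after its value had been seen), stress response genes 0.68 with 2 of 9 (hsp90 at 2.10-fold, and hsp16 at 2.39-fold, named after its value had been seen), ribosomal proteins 0.70 with 0 of 131, and the phosphate regulon 0.78 with 0 of 2. Their percentiles among 10000 random lists of the same size, matched on mean expression, lay between 32.4 and 81.0, as a description of these libraries. No meiotic gene with a DSR element reached 100 reads, and mei4, the meiotic forkhead factor, had 26.5 and 33 reads.

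The remaining lists lay outside the central 95% of random lists in dcr1 delta. Glycolytic genes had a median log2 ratio of 0.81, with tdh1 at 1.81-fold and eno101 at 1.86-fold, at percentile 100. That median was near the general shift, whereas random lists matched to it on mean expression had a median of 0.22. Those lists were drawn from genes of every RNA class, not from protein-coding genes alone. The percentile therefore does not set glycolytic genes apart from other mRNA. Structural non-coding RNAs had a median of 0.17 (percentile 1.74), below the shift. Among them snu1, the U1 spliceosomal RNA, was lower (0.356, 0.338 to 0.374), snu2 (1.11) and snu6 (1.13) stood near 1, and srp7, the RNA of the signal recognition particle, was at 1.45-fold. Tf2 retrotransposons had a median of 0.53 (percentile 0.30), with Tf2-1, Tf2-2, Tf2-3 and Tf2-6 between 1.44-fold and 1.45-fold, and their copies share reads. Scaling by the median of ratios moves all genes alike and brings the medians of structural non-coding RNAs, Tf2 and subtelomeric protein genes below 0, to -0.55, -0.19 and -0.38. The 2 helicases had a median of -5.05 (percentile 0.27). As Tf2 copies, and both helicases, share nearly all their reads, their percentiles overstate how far these lists stand apart. Subtelomeric protein genes had a median of 0.34 (percentile 0.09) over 7 members, of which 3 were lower (tlh1, tlh2 and SPAC212.06C) and 3 higher (SPAC750.01 at 2.12-fold, plb4 and SPBC1348.10C), while gdt1 was at 1.26-fold. Relative to the shift SPAC750.01 was at 1.22 and gdt1 at 0.726. With the shift removed, 0 of 42 subtelomeric gene strands were at least 2-fold higher. With a minimum of 30 reads the median was -0.27 over 13 members, and with 500 reads -5.01 over 3. SPAC212.06C, plb4 and SPBC1348.10C were named after their values had been seen.

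The comparison of NLS-swi6-KR25A with wild type asked which small RNAs differed in the strain with this swi6 allele. No library carried the nuclear localization signal without the hinge mutation, so the effects of these changes cannot be told apart. Most centromeric small RNA was present at near wild-type level, but small RNA from the outer edges of centromere 3 was nearly gone, that of centromere 1 was far lower and that of centromere 2 was lower. Small RNA from the ends of chromosomes I and II with tlh1 and tlh2 was more abundant than in wild type (4.97-fold and 4.84-fold). These ends share reads and are not separate measurements. Centromeric small RNA as a whole was at 26009 RPM against 35114 (ratio 0.741, 0.738 to 0.743), and subtelomeric small RNA at 4396 against 1045 RPM (ratio 4.21, 4.15 to 4.27). The median protein-coding gene differed by 0.07 on the log2 scale.

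By centromere, the ratio was 0.751 (0.745 to 0.756) at centromere 1, 0.904 (0.898 to 0.911) at centromere 2 and 0.684 (0.681 to 0.687) at centromere 3. An edge was defined as the outermost 1500 bases with Dicer-dependent small RNA in wild type, after the loss in NLS-swi6-KR25A had been seen in wider windows. At centromere 3, the left edge (chromosome III, 1069501 to 1071000) went from 1480 to 10.9 RPM, a ratio of 0.00733 (0.00659 to 0.00814), and the right edge (1140751 to 1142250) from 2846 to 9.48 RPM, a ratio of 0.00333 (0.00297 to 0.00373), which is 300-fold lower. At centromere 1 the left edge (chromosome I, 3752751 to 3754250) had a ratio of 0.107 (0.104 to 0.112) and the right edge (3788751 to 3790250) one of 0.142 (0.137 to 0.146). The inverted repeats IRC1-L (3753160 to 3753692) and IRC1-R (3789400 to 3789948), which border centromere 1, had ratios of 0.0657 (0.0613 to 0.0703) and 0.0705 (0.0661 to 0.0752). At centromere 2 the edges had ratios of 0.694 (0.671 to 0.717) on the left and 0.704 (0.688 to 0.721) on the right. Outside the 6 edges the centromeres were at 0.901 (0.898 to 0.904) of wild type. On the right of centromere 3 the loss ran further inward than the 1500 bases of the edge. Windows there had ratios from 0.00669 at 1500 bases inward to 0.00972 at 2250, and 0.511 at 2500. They are counted as outside the edges. Where only reads with every position in the edges of 1 centromere were counted, the ratios were 0.0248 (0.0232 to 0.0264) for centromere 1, 0.346 (0.332 to 0.361) for centromere 2 and 0.00340 (0.00305 to 0.00378) for centromere 3.

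**Figure D2:**
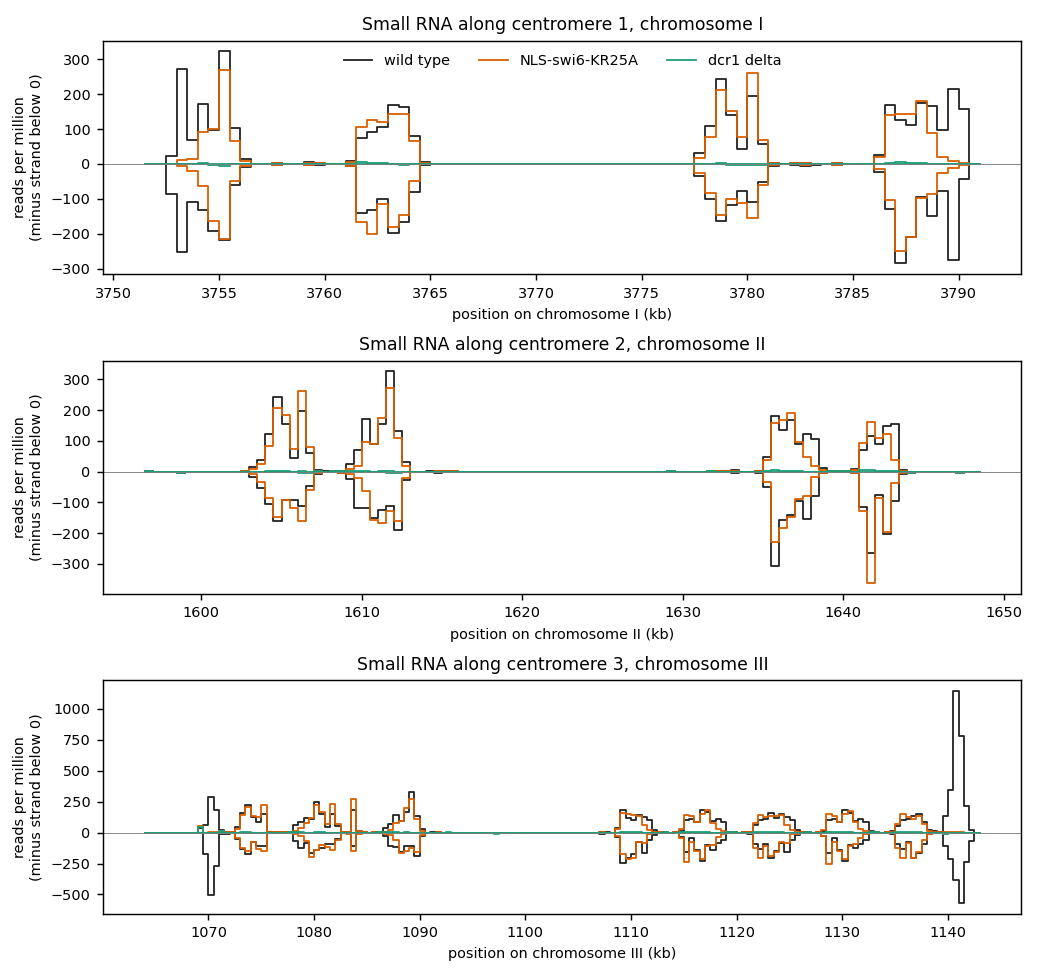
RPM in windows of 500 bases (y axis, plus strand above 0 and minus strand below 0) along each centromere (x axis, position in kb) for the 3 libraries. The wild-type peaks in the edges of centromere 3 have no visible NLS-swi6-KR25A counterpart (edge ratios 0.00733 and 0.00333), and the dcr1 delta line lies at 12.2 RPM or less except in the plus-strand window just outside the left edge (chromosome III, 1069001 to 1069500), which was at 35.0 RPM in wild type, 53.1 in NLS-swi6-KR25A and 47.8 in dcr1 delta.

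**Figure D3:**
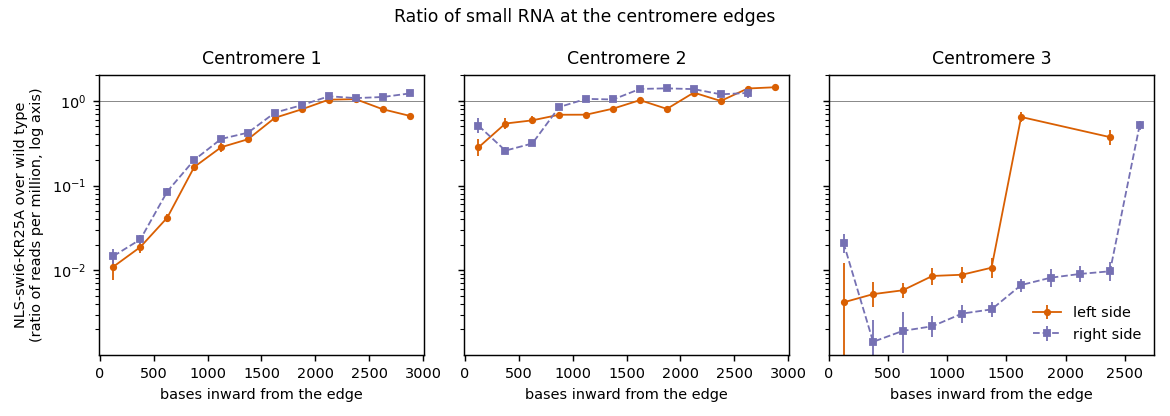
Ratio of NLS-swi6-KR25A to wild type (y axis, log axis) in windows of 250 bases with at least 10 wild-type RPM, by distance inward from each edge in bases (x axis), with 95% intervals of counting error as bars. At centromere 1 the ratio was 0.0110 in the outermost left window and 0.0147 in the outermost right one; from 750 bases inward on both sides of centromeres 1 and 2 and on the left of centromere 3, all reads also matched outside the edges of that centromere, as did all but 9.48% of wild-type reads 500 bases inward on the left of centromere 3, so that the ratios there do not measure that locus alone.

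Reads of 1 position made up 10.7% of wild-type centromeric reads. With these alone, the centromeric log2 ratio was -2.42 rather than -0.43. Such reads had a ratio of 0.0385 in the 6 edges and 0.968 outside them. The centromere 1 edges held 0 distinct sequences with 1 perfect position and gave no ratio of this kind. Ratios were 0.554 (left) and 0.297 (right) at the centromere 2 edges, and 0.00395 and 0.00325 at those of centromere 3. In NLS-swi6-KR25A, 0.728% of centromere 3 reads had 1 position, against 14.5% in wild type. At centromeres 1 and 2 these shares were 3.88% and 6.10%, against 2.94% and 7.83%. The loss of reads with 1 position was thus mostly at centromere 3. Of the 233 centromeric features, tRNA genes included, 66 were at least 2-fold lower in NLS-swi6-KR25A and 1 was higher. The 11 lowest ratios all belonged to non-coding RNAs at the outer ends of centromere 3. SPNCRNA.7236 went from 678 to 1.23 sense RPM, 558-fold lower (ratio 0.00179, 0.00128 to 0.00244). SPNCRNA.7235 was 315-fold lower on the sense strand and 330-fold lower on the antisense strand, and SPNCRNA.7234 155-fold and 148-fold. At the left end, SPNCRNA.7185 was 162-fold lower (sense) and 205-fold lower (antisense). SPNCRNA.7184 (1069629 to 1069837) kept 3 reads per strand, with ratios of 0.00903 (0.00185 to 0.0268) sense and 0.00272 (0.000559 to 0.00797) antisense. SPNCRNA.7183 (1069351 to 1069715) kept 1 sense read, with a ratio of 0.00726 (0.00149 to 0.0215), and 3 antisense reads, with 0.0102 (0.00208 to 0.0303). Antisense reads of SPNCRNA.7566, the last of the 12 lowest, went from 7907 to 448, but these were reads of ACAGTCCGACGATC, the end of the adapter, which matches 14 bases of chromosome III (1964511 to 1964524, minus strand). The exact sequence had 7812 reads in wild type, 393 in NLS-swi6-KR25A and 1201 in dcr1 delta, and 135869, 6989 and 24915 reads ended with it, so that the wild-type library carried most reads of this kind.

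At the chromosome ends, the left end of chromosome I was 4.97-fold higher (4.86 to 5.09) and the right end of chromosome II 4.84-fold higher (4.73 to 4.96). Of their NLS-swi6-KR25A reads, 1.52% and 0.893% had 1 position. The other reads were split between their positions, so the values of these ends are not separate measurements. The right end of chromosome I was lower, at 0.625 (0.592 to 0.661), and the left end of chromosome II was at 1.15 (1.05 to 1.25). Windows of 5000 bases within an end went both ways: on chromosome I, bases 5001 to 10000 were 6.80-fold higher (6.55 to 7.06) and bases 15001 to 20000 were at 0.455 (0.421 to 0.491), and on chromosome II, bases 4519805 to 4524804 were 31.9-fold higher (22.8 to 46.3) and bases 4514805 to 4519804 at 0.534 (0.498 to 0.572). Bases 5569134 to 5574133 of chromosome I were at 0.404 (0.375 to 0.435). Reads with 1 position moved further in the windows where they could be compared, except bases 5539134 to 5544133 of chromosome I (0.942, against 0.943 for all reads). They gave 0.0323 in bases 4514805 to 4519804 of chromosome II and 0.142 in bases 5569134 to 5574133 of chromosome I. In higher windows they gave 78.0 (chromosome I, 5001 to 10000) and 7.52 (chromosome II, 4524805 to 4529804). The helicase gene tlh1 was 4.73-fold higher on the sense strand (4.55 to 4.92) and 5.16-fold on the antisense strand (4.96 to 5.36), and tlh2 4.71-fold and 5.11-fold. In all, 40 of 64 subtelomeric features were at least 2-fold higher and 8 lower. Only 1.48% of the subtelomeric reads of NLS-swi6-KR25A had 1 position, so features or windows that share reads are not separate measurements. Subtelomeric reads with 1 position in the genome had a log2 ratio of 1.05, against 2.07 for all. Around mat3, 85.5 reads against 30 gave a ratio of 1.59 (1.04 to 2.49).

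**Figure D4:**
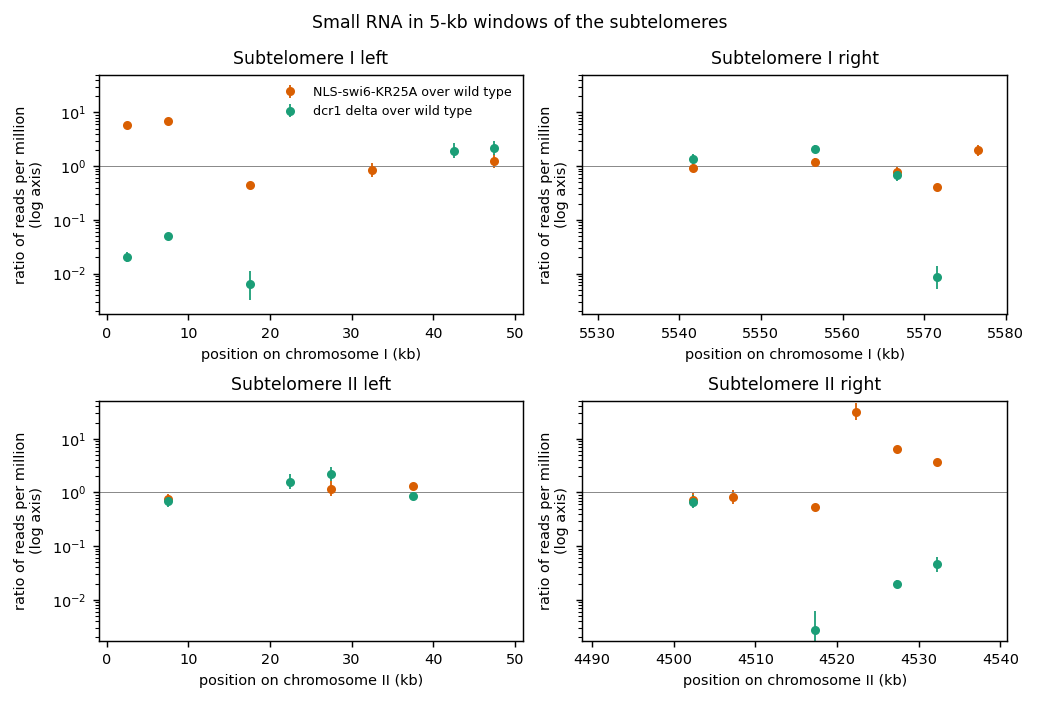
Ratio to wild type (y axis, log axis) of NLS-swi6-KR25A and of dcr1 delta in windows of 5000 bases along the 4 subtelomeres (x axis, position in kb), for windows with at least 100 reads in either library compared, with 95% intervals of counting error as bars. The windows at 1 to 5000 and 5001 to 10000 of chromosome I were 5.73-fold and 6.80-fold higher in NLS-swi6-KR25A and at 0.0206 and 0.0499 in dcr1 delta.

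The highest ratios in NLS-swi6-KR25A lay in subtelomeric pseudogenes and non-coding RNAs. Antisense reads of the pseudogene SPBCPT2R1.07C (chromosome II, 4523274 to 4524970) went from 0.183 to 34.2 RPM, and those of its copy SPAC212.09C (chromosome I, 7619 to 9274) from 0.183 to 32.5 RPM. With their 3.33 wild-type reads rounded to 3, the ratios were 208 (71.0 to 1010) and 198 (67.4 to 960). The pseudogene SPAC212.10 was 41.8-fold higher antisense (33.3 to 53.3) and 34.4-fold higher sense (24.8 to 49.3), and SPBCPT2R1.10 was 30.5-fold higher. The non-coding RNAs SPNCRNA.6644 (129, 43.9 to 626), SPNCRNA.2006 (106, 48.6 to 290 sense; 21.8 antisense) and SPNCRNA.6645 (55.4, 18.8 to 270 sense; 46.7, 18.1 to 172 antisense) followed. Nearly all reads of these features matched several places, so the copy of origin is uncertain. SPNCRNA.6644 lies opposite SPBCPT2R1.07C, and SPNCRNA.2006 partly opposite SPAC212.09C. Their sense reads therefore include antisense reads of those pseudogenes and are not independent of them. Away from the chromosome ends, SPNCRNA.4210 (chromosome I, 4911428 to 4913807) was 22.2-fold higher (14.5 to 35.5), but 26.2% of its reads had 1 position and those gave 12.4-fold. Antisense reads of mae2, which encodes malic enzyme, were at a ratio of 22.9 (7.66 to 113) with 3 reads in wild type, and 17.9% of them had 1 position. Antisense reads of swi6 itself went from 1.70 to 5.10 RPM (interval of the ratio 2.04 to 4.56), with 31 reads in wild type and 168 in NLS-swi6-KR25A, and sense reads were at 1.35 (1.11 to 1.65).

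Over all gene strands with at least 100 reads, 58 of 6184 were at least 2-fold higher and 117 lower in NLS-swi6-KR25A. Outside centromeres and subtelomeres 17 were higher and 43 lower of 5887. With the shift of 0.07 removed these were 9 and 49, and by the median of ratios 13 and 45. Scaling by snRNA, snoRNA and structural non-coding RNA gave 23 and 41, and by mapped reads other than rRNA and tRNA 15 and 44. Of the fixed lists, 2 lay outside the central 95% of random lists. Tf2 retrotransposons had a median log2 ratio of -0.68 (percentile 0) over 13 members, 0 of them beyond 2-fold, with Tf2-1, Tf2-2, Tf2-3 and Tf2-6 all at 0.624. The helicases had a median of 2.24 (percentile 100). The copies in each of these lists share nearly all their reads and are not separate measurements, so that percentiles against lists of separate genes overstate how far both stand apart. Structural non-coding RNAs had a median of -0.14 (percentile 2.51) with 1 of 10 beyond 2-fold: snu1, the U1 RNA, went from 267 to 58.6 RPM (0.219, 0.208 to 0.231), while snu2 (0.955), snu6 (1.09) and srp7 (0.997) stood near 1.

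The other groups showed 0 members beyond 2-fold in NLS-swi6-KR25A, apart from the subtelomeric protein genes. RNAi and heterochromatin factors (17 members, median log2 ratio 0.17, percentile 94.6) included clr3 (1.02), epe1 (1.13) and rik1 (1.33). RNA elimination factors (9 members, 0.11, percentile 80.8) included mtr4 (1.13), dis3 (1.08), mmi1 (1.17) and mtl1 (1.12). Glycolysis (10 members, 0.16, percentile 92.2) included tdh1 (1.12), eno101 (1.24) and pdc101 (0.997), and histones (10 members, 0.08, percentile 47.8) included hta1 (1.06) and hhf1 (1.23). Stress response genes (9 members, 0.01, percentile 13.4), the phosphate regulon (2 members, 0.26, percentile 90.0) and ribosomal proteins (131 members, 0.08, percentile 50.8) were also near wild type, with hsp90 at 1.01, pho1 at 1.28 and rpl8 at 1.20. Among meiotic genes only mug8 reached 100 reads (1.28, 0.894 to 1.86), at percentile 45.1. Subtelomeric protein genes (12 members, 0.07, percentile 31.3) held tlh1, tlh2 and SPAC750.08C (7.03-fold higher) on one side and SPAC212.06C (0.437) on the other, the last pair named after their values had been seen, and SPAC750.01 was at 1.20. With a minimum of 30 reads the median of this list was 0.32 over 16 members (percentile 99.1), and with 500 reads 2.23 over 3 (percentile 100).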

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

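The tests of deletion and scaling at the centromere edges, of reads with every position in the subtelomeres, of repeat copy number and of mRNA scaling were chosen after the results were seen, and the first test of a deletion at centromere 1 was replaced because its windows held only reads shared with other loci; the tests on reads of 20 to 24 bases, on reads with 1 position and without the top genes were written before.

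Reads without a genome position were not used in any comparison, and some of them matched once their last 2 or 3 bases were removed. In 8 cases such reads were above their wild-type level. In dcr1 delta, reads of this kind from sense mRNA were at 79.6 RPM against 48.1 RPM in wild type, from rRNA at 87.2 against 62.4 RPM, and from unannotated sequence at 4.37 against 1.98 RPM. Those from the antisense strand and spacer of rDNA were at 80.0 RPM in dcr1 delta and 25.0 RPM in NLS-swi6-KR25A, against 20.9 RPM in wild type. Those from tRNA were at 6049 RPM in dcr1 delta against 5615 RPM. In NLS-swi6-KR25A, such reads from the subtelomeres were at 85.0 RPM against 23.7 RPM, and those matching several classes at 6.47 against 3.24 RPM.

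Small RNA of the centromere 1 and 3 edges was lower in NLS-swi6-KR25A (ratio 0.0427), and the tables argue against scaling or depth as the cause, since the ratio outside the edges was 21.1 times that inside, and against a different gel window, since reads of 20 to 24 bases had a ratio of 0.0389. Over all 6 edges, with centromere 2 included, the ratio was 0.138, and 0.126 among reads of 20 to 24 bases. A complete deletion of the centromere 1 edges was not settled. Reads found in those edges alone had a ratio 7.29 times (6.15 to 8.66) that of the same kind of reads in the centromere 3 edges. A complete deletion would leave spill-over between libraries. Reads with 1 mismatch were not left out, so reads of other repeats could also remain. The centromere 1 ratios rose inward over 500 bases, from 0.0113 to 0.0374 on the left and from 0.0147 to 0.0494 on the right. The comparison also takes spill-over to be alike along the edges. Of the 9 centromere 3 windows with such reads, 8 had ratios between 0.00143 and 0.00482. The outermost on the right had 0.0211 (0.0161 to 0.0271), above the outermost windows of centromere 1 (0.0113 and 0.0147). For centromere 3 a deletion in this strain cannot be told apart from a loss of small RNA, because only 37 distinct sequences with 1 perfect position in its edges were seen in that library and in neither other, beside 11 seen in dcr1 delta alone. An effect of the swi6 allele, through the hinge mutation or the added nuclear localization signal, stays open as a hypothesis. So does a complete or partial deletion or a mixed culture, and 1 library per strain cannot separate the allele from the strain.

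Subtelomeric small RNA was higher in NLS-swi6-KR25A (ratio 4.21). The tables argue against reads shared with positions outside the subtelomeres, since reads with every position inside had a ratio of 4.40 (4.33 to 4.47), and against a different gel window, since reads of 20 to 24 bases had a ratio of 3.92. Reads with 1 position had a ratio of 2.08 (1.89 to 2.28), an interval that spans the bound of 2 set beforehand, so that sharing among repeats was left undecided by that test. That pooled value mixes windows that went both ways. Where a window had at least 100 such reads in either library, they gave 78.0 (chromosome I, 5001 to 10000) and 7.52 (chromosome II, 4524805 to 4529804). The others gave 0.942 and 0.142 (chromosome I, from 5539134 and 5569134) and 0.0323 (chromosome II, from 4514805). The rise in the first pair was thus not limited to shared reads. Of 19 windows of 5 kb with at least 100 reads, 3 were at least 1.5 times lower and 6 at least 1.5 times higher, which leaves a different number of repeat copies in single windows open. Windows that share reads between copies are not separate measurements. An effect of the swi6 allele, through the hinge mutation or the added nuclear localization signal, may contribute and was not tested apart from the strain.

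Sense mRNA reads were higher in dcr1 delta (ratio 1.65). The tables argue against a few abundant genes, since the ratio without the 20 genes with most reads was 1.65, and against a different gel window, since reads of 20 to 24 bases had a ratio of 1.53. How far scaling accounts for it stays open: per snRNA, snoRNA and structural non-coding RNA read the ratio was 1.17 (1.16 to 1.17), between the bounds of 1.1 and 1.3, whereas per mapped read other than rRNA and tRNA it was 1.74 (1.74 to 1.75), and the 0.998 found by the median of ratios decides nothing, since that scaling centres the genes by construction. The loss of centromeric and subtelomeric reads from the total may account for a small part, as the ratio was 1.59 with those reads left out of the totals. Whether mRNA fragments were more abundant per cell in dcr1 delta cannot be told apart from the scaling.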

How the results depend on the processing

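Tests on reads of 18 to 28 bases and on other treatments of tRNA genes were chosen after the data were seen; all others here were planned. Of 126 alternatives to the main results, 53 left the value within its counting interval or its count within 1.5 times, 73 moved it and 0 reversed it. Of 1061 alternatives to other results, 712 left the value so, 344 moved it and 5 reversed it. A reversal was defined only as a change of sign in a log2 ratio, so counts and shares could not be recorded as reversed. The dcr1 delta calls, 1565 higher and 217 lower, became 47 and 301 by the median of ratios and were recorded only as counts. No paired analysis was possible because each group had 1 library. Unless stated, the cause was not tested.

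The log2 ratio of centromeric small RNA in NLS-swi6-KR25A, -0.43, was -0.45 per read other than rRNA and tRNA, -0.46 by the median of ratios, -0.37 by structural RNA, -0.56 with 20 to 24 bases, -2.42 with 1 position, -0.16 with positions in full, -0.56 with distinct sequences, -0.44 with perfect matches, -0.44 with 18 to 28 bases, -0.42 with tRNA genes left out on the annotated strand only and -0.0457 with them kept. In dcr1 delta, -6.16 became -6.07, -6.88, -6.66, -6.82, -5.49, -6.21, -4.52, -5.88, -6.21, -4.88 and -0.55 in the same order. The tRNA values follow from reads at tRNA-Asp and other tRNA genes, which wild type and dcr1 delta share.

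The subtelomeric log2 ratio in NLS-swi6-KR25A, 2.07, was 2.04 by the median of ratios, 2.14 by structural RNA, 1.97 with 20 to 24 bases, 1.05 with 1 position, 1.79 with positions in full and 1.35 with distinct sequences. In dcr1 delta, -2.82 became -2.74 per read other than rRNA and tRNA, -3.54 by the median of ratios, -3.32 by structural RNA, -3.44 with 20 to 24 bases, -0.41 with 1 position, -2.99 with positions in full, -2.57 with distinct sequences and -2.56 with perfect matches. The mat3 log2 ratio in dcr1 delta, 0.74, was 0.0219 by the median of ratios.

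In NLS-swi6-KR25A, the 58 higher gene strands became 20 with 1 position and 128 at 30 reads, and the 117 lower ones 45 with 1 position and 74 at 4-fold. In dcr1 delta, the 1565 higher ones became 47 by the median of ratios, 128 by structural RNA, 703 with 20 to 24 bases, 2782 at 30 reads, 343 at 500 reads and 20 at 4-fold, and the 217 lower ones became 39 with 1 position. Read minimums and the 4-fold rule change the counts by construction.

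The share of rRNA and tRNA was 11.3% (wild type), 7.58% (NLS-swi6-KR25A) and 7.73% (dcr1 delta) with distinct sequences and 7.98%, 7.55% and 8.24% with 1 position. Centromeric reads of 20 to 24 bases were 66.8%, 67.1% and 59.8% with distinct sequences and 82.0%, 79.3% and 68.9% with 1 position, and those beginning with U 53.9%, 53.4% and 36.9%, and 68.5%, 70.4% and 18.6%. Plus-strand centromeric reads were 50.0% (wild type) and 49.1% (dcr1 delta) with distinct sequences, and 58.3%, 41.2% and 61.9% in the 3 libraries with 1 position. Lists outside the central 95% of random lists went from 2 to 4 at 30 reads in NLS-swi6-KR25A, with subtelomeric protein genes (0.32, percentile 99.1) and structural non-coding RNAs (percentile 2.41) added. In dcr1 delta the 5 lists became 6 at 30 reads, with the meiotic genes added (0.0868 over 4 members, percentile 0.57), and 3 at 500 reads. In NLS-swi6-KR25A, subtelomeric protein genes were also outside at 500 reads (2.23, percentile 100). In dcr1 delta the medians of structural non-coding RNAs, Tf2 and subtelomeric protein genes were -0.55, -0.19 and -0.38 by the median of ratios, which follows from a shift common to all genes and says nothing about these lists. The median of subtelomeric protein genes was also reversed at 30 reads (-0.27, more members) and at 500 reads (-5.01, fewer members). Depth limits the mat3 interval, with 30 reads in wild type, and those of genes with few wild-type reads.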

Other observations

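No test of an explanation was run in this part, and all values here were singled out after the data were seen.

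Fragments of tRNA differed by amino acid in NLS-swi6-KR25A. Those of tRNA-Trp were at a ratio of 0.147 (0.144 to 0.150), tRNA-Ala at 0.280 (0.276 to 0.283), tRNA-Lys at 0.314 (0.311 to 0.316) and tRNA-Tyr at 0.587 (0.575 to 0.599), while tRNA-Asn was at 1.87 (1.86 to 1.89), tRNA-Ser at 1.75 (1.74 to 1.77) and tRNA-Leu at 1.59 (1.59 to 1.60). Among reads of 20 to 24 bases the same tRNAs gave 0.113, 0.180, 0.375, 0.684, 1.47, 2.03 and 1.29, but read length moved 4 of the 20 tRNAs to the other side of 1: tRNA-Gly from 0.664 (0.662 to 0.666) to 1.05, tRNA-Val from 1.15 to 0.998, tRNA-Pro from 1.12 to 0.826 and tRNA-Ile from 1.04 to 0.752. In dcr1 delta, tRNA-Trp was at 0.916, tRNA-Ala at 0.834 and tRNA-Lys at 0.953. Reads of 28 nucleotides, the upper end of the gel window, made up 12.1% of mapped reads in wild type, 5.47% in NLS-swi6-KR25A and 5.14% in dcr1 delta.

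Centromeric reads of 20 to 24 bases often carried a last base absent from the genome. In wild type 17.3% (17.2 to 17.4) did, with U on 8.54% and A on 6.90%, and in NLS-swi6-KR25A 16.5% (16.4 to 16.6), with U on 8.68% and A on 5.98%. Of the 7187 such reads in dcr1 delta, 1.98% (1.67 to 2.32) did, with U on 0.570% and A on 1.09%.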
